A study of Danio rerio with 6 samples.

How the data were processed

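Brain RNA of 6 samples of female zebrafish of the AB strain, all 12 months old, was profiled on 1-colour Agilent arrays after Cy3 labelling. Embryos had been kept in water with 0 or 10 ppb lead acetate from under 2 to 72 hours post fertilization and then raised in clean water, per the labels' protocols. There were 3 control arrays (0 ppb) and 3 lead arrays (10 ppb), and each sample's group was taken from its label. The labels number the replicates but do not say that they were separate animals, so the p-values measure the spread between these samples only. Male brains, which the series' design text also mentions, were not analysed here.

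Each array file holds the intensity of 180880 spots, which the authors deposited as written by Agilent Feature Extraction 11.5, per the file headers and the submitters' processing notes. The processed intensity is background-subtracted and detrended within the array, per the file headers, and has not been scaled between arrays. A further table, which the authors deposited for the series, holds a log2 ratio and a p-value for 4930 probes. The table is named as probes altered in lead-exposed females, which would read as lead over control, but neither its name nor its header states which group the ratio is over. Its test and normalization are not given in the sources used here. No listed log2 ratio was smaller in size than 0.585 and no listed p-value in the authors' deposited table exceeded 0.05.

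Control spots were left out, which left 176026 spots of 128291 probes, with 1 to 3 spots per probe. Spots that the scanner software marked as outliers were treated as missing. The log2 processed signals of a probe's spots were averaged, and the array's 75th percentile over all probes was subtracted. A probe was tested when it was well above background on at least 3 of the 6 arrays. That filter kept 89770 probes and left out 38521, and 89759 of those kept had enough values for the fit. Lead and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are given as lead minus control on the log2 scale, and a level is a log2 signal relative to the array's 75th percentile. Where no array of a group was well above background at a probe, the fold rests on dim signals and holds on the scale used here only. It sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array. That floor left the difference unchanged at the probes named this way below, so their folds are not firm lower bounds.

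Genes were named by matching the accession of a probe, without its version, to a RefSeq table of assembly GRCz12tu, which was used for names only. A RefSeq symbol was found for 39952 of 128291 probes (31.1%), which covered 13547 symbols, and 13500 of the 14239 curated mRNA accessions matched. Other probes are unnamed here. Array files of this series give no position of a probe on that assembly, so no coordinates are printed. Symbols printed in capitals are those of the authors' deposited table.

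For each of 35 gene lists fixed before the data were examined, 1 probe per gene was taken, the one with the highest mean signal, which gave 12401 genes. The lists were tested with limma's camera, which asks whether a list's genes rank higher or lower than all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 35 lists. The same test with a correlation estimated from the residuals, and limma's fry, which tests a list's genes alone, were run as alternatives. Genes were named by a rule fixed before the data were examined. It took the 12 genes with higher and the 12 with lower lead means that had the smallest unadjusted p among probes whose groups did not overlap, the members with the smallest p of each list, the 5 largest positive and 5 largest negative ratios of the authors' deposited table, and list members that passed adjustment over their list alone. Clone and locus identifiers were skipped.

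The fit was tested on simulated arrays drawn from the means and spreads of 83361 probes with complete values. With no change simulated, 5.3% of probes had an unadjusted p under 0.05 and 0 passed adjustment. With 50 probes changed at each size, 0 of 50 passed adjustment at 1.5-fold, 0 of 50 at 2-fold, 2 of 50 at 4-fold and 17 of 50 at 8-fold. The unadjusted p was under 0.05 for 22, 38, 45 and 45 of these, in that order. On 12401 simulated independent genes, a shift of 0.25 given to the 66 cell cycle genes was called by camera with either correlation, and no other list was called. Probes, or genes of a list, that vary together were not simulated. The simulation therefore does not check how often probes or lists are called falsely on the real arrays, and the numbers found hold for the simulated arrays only.

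Alternatives were normexp background correction with offset 50, quantile, median and cyclic loess normalization, other filters on dim probes, slide as a fixed or random block, slide 1 alone, a replicate block, other variance models, outlier spots kept, and each array left out in turn. Normexp was run on the median spot signal, because the mean spot signal was not among the columns used here. After the data were examined, fits with control replicate 2 as the only control array, and with the mean of the muscle genes as a covariate, were added. That mean itself separates the groups, so as a covariate it can take up a group difference whatever its cause. The precision is limited by the number of arrays. Slide 1 held replicates 1 and 2 of both groups and slide 2 held replicate 3 of both. Every control array lay at an odd position on its slide and every lead array at an even one, so array position and group cannot be told apart. Figures were drawn with matplotlib 3.10.9.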

Results

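Gene expression was measured in the brains of 12-month-old female zebrafish that had been exposed to 10 ppb lead as embryos, up to 72 hours post fertilization, and in control females raised without lead. The question, as the series' title states it, was which genes of the aged brain differ after this early exposure, with nervous system development and Alzheimer's disease as the named themes. There were 3 arrays per group. Between 65.4% and 73.8% of the 128291 probes were well above background on an array, and the 75th percentile of the processed signal ran from 362.3 on lead replicate 2 to 604.2 on lead replicate 3. No spot was saturated. Outlier-marked spots made up 7.03% of control replicate 1, 3.21% of lead replicate 3 and at most 1.53% of the other arrays. Correlations between arrays, across probes, lay between 0.924 and 0.968, and control replicate 3 had the lowest mean correlation with the others, 0.929.

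The direction of all differences below rests on the sample labels, and the authors' deposited table runs the other way. All 4928 of its probes that had values in both groups showed the opposite sign here, with a correlation across probes of -0.998. Of the 4731 listed probes with values on all 6 arrays, 4731 lay within 0.002 of the mirrored ratio after a constant offset of -0.076 was removed. The other 199 had an outlier-marked array, and 0 of them lay within 0.002 with those spots missing. With outlier spots kept 191 of the 199 did, and all 199 had the opposite sign. Under that setting 4314 of the 4342 tested listed probes had the opposite sign, so neither treatment of outlier spots matched the table throughout. Apart from the remaining 8, each listed ratio was mirrored with outlier spots either missing or kept. The values do not settle whether the table gives control over lead or the labels of the 2 groups were exchanged. Below, lead arrays and control arrays mean the arrays labelled so.

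**Figure D1:**
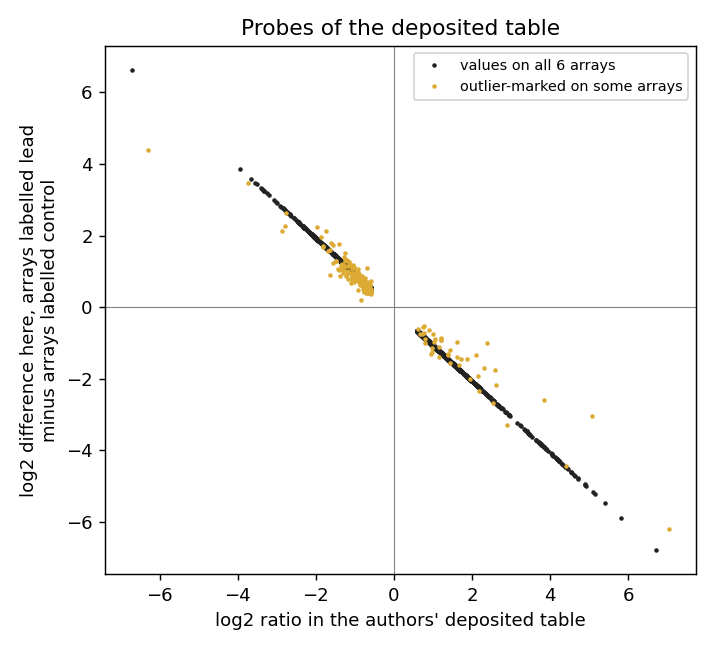
Each point is a probe of the authors' deposited table, with the table's log2 ratio on the x axis and the log2 difference between the arrays labelled lead and those labelled control on the y axis. The 4731 probes with values on all 6 arrays lie on a line of falling slope, and all 4928 probes have opposite signs on the axes.

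One gene passed adjustment over all probes. A probe of ggcta, a gamma-glutamylcyclotransferase of the glutathione cycle, was at -0.62 ± 0.21 (SD, n = 3) on the lead arrays and not well above background on any of the 3 control arrays (-7.24 ± 0.55). The probe was 98.9-fold higher on lead arrays on the scale used here (log2 difference 6.63 ± 0.33 SE, limma adjusted p = 0.0389). That fold is set by control signals not well above background, so it is not a firm lower bound. The brighter of the 2 tested ggcta probes differed the other way, by -0.31, with levels of 1.13 ± 0.29 on control and 0.82 ± 0.29 on lead arrays, so the ggcta probes disagreed in sign. The call ended with slide as a block (adjusted p = 0.0526) and when any 1 of the 6 arrays was left out (adjusted p between 0.091 and 0.282). With normexp and quantile normalization the log2 difference of ggcta was 2.89.

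Below that threshold, the genes with the smallest unadjusted p whose groups did not overlap had an adjusted p of 0.584 and are given as values. Among those higher on lead arrays, socs3a, a feedback inhibitor of cytokine signalling, was at 2.48 ± 0.39 against 0.24 ± 0.51 on control arrays, 4.73-fold. The ribonucleotide reductase gene rrm2l was 2.51-fold higher, and all 10 of its other probes had the same sign, 9 of them at unadjusted p under 0.05. The glucose-6-phosphatase gene g6pc3 was 2.90-fold, the dynein regulatory complex gene drc4 2.41-fold, the kinase gene cdk15 2.56-fold, the nutrient-sensing gene mios 3.35-fold and rtkn2, well above background on 2 of 3 control arrays, 3.06-fold higher. Probes of mei4, of the spindle gene ska1, of gbgt1l4 and of ribc1 were not well above background on any control array. They were 6.62, 4.80, 4.21 and 4.54-fold higher on lead arrays. These folds rest on dim control signals and hold on the scale used here only. Over the settings tried the log2 differences were as small as 0.69, 0.415, 0.451 and 0.63, in that order.

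Among those lower on lead arrays, asic2, an acid-sensing ion channel, was at 1.87 ± 0.09 against 3.50 ± 0.41 on control arrays, 3.11-fold. The 5'-nucleotidase gene nt5e was 3.41-fold, the keratin gene krt4 3.08-fold, traf7 2.96-fold and the muscle creatine kinase gene ckma 2.92-fold lower. The mitochondrial fusion gene mfn1b was 2.79-fold, the poly(A) ribonuclease gene parn 2.63-fold and the plasma membrane calcium pump gene atp2b3a 2.54-fold lower. The remaining genes were snap23.2 (2.43-fold), igf2r (2.46-fold), cdkal1 (2.21-fold) and pid1, whose probe was well above background on 1 of 3 lead arrays and differed by -1.49 ± 0.22 (SE), and by -0.25 with normexp and the 75th percentile. All 14 other krt4 probes and all 3 other cdkal1 probes had the same sign, whereas of the other traf7 probes 1 of 3 did.

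**Figure D2:**
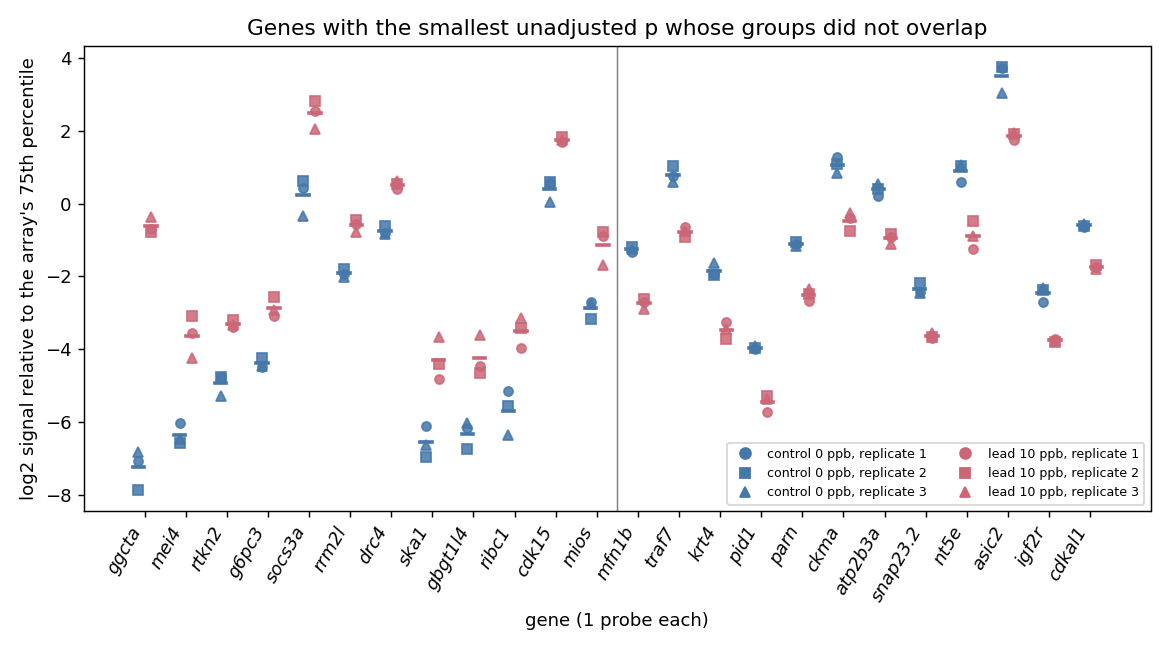
Log2 signal relative to the array's 75th percentile for 1 probe of each of 24 genes, with 1 point per array and a bar at the mean of the 3 arrays of a group. The 12 genes left of the grey line were higher on lead arrays and the 12 to the right were lower, and ggcta alone passed adjustment (adjusted p = 0.0389).

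Of 89759 probes, 7403 had an unadjusted p under 0.05 (8.25%, where chance gives 4488), 3180 of them higher and 4223 lower on lead arrays. A difference of at least 1.5-fold as well was seen for 6937, of which 2937 were higher and 4000 lower. The groups did not overlap at 16.5% of the 83361 probes with complete values, where chance gives 10%. The direction of this set depended on the scaling. The share higher on lead arrays was 43% here, 71.7% with median scaling, 58.2% with quantile normalization, 59.4% and 58.5% with normexp, and 50% with cyclic loess. Median scaling moved the median difference of all probes from -0.03 to 0.16, so a difference of that size has no settled sign. With slide as a block 0 probes passed adjustment and 9257 had an unadjusted p under 0.05, and within slide 1 the numbers were 0 and 6825. Without lead replicate 1 the unadjusted number was 4701.

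Of the 35 lists, skeletal muscle had the median difference farthest from 0. Of the 62 measured muscle genes 53 were lower on lead arrays, 26 of them at unadjusted p under 0.05, and the median difference was -1.84 (camera adjusted p = 6.47e-18, and adjusted p = 0.93 with an estimated correlation). Fast myosin heavy chains led the list: myhc4 was at 3.52 ± 1.99 on control and -1.20 ± 0.53 on lead arrays, 26.3-fold lower, myhz2 was 25.8-fold and myhz1.1 18.9-fold lower. The brightest ckma probe was 19.8-fold lower. No muscle gene passed adjustment over all probes or adjusted over the list alone, where the smallest adjusted p was 0.0693. The control arrays differed among themselves by more than the groups did. The mean of the 62 genes was 0.80, -0.42 and 2.3 on control replicates 1, 2 and 3 and -1.20, -0.67 and -1.37 on lead replicates 1, 2 and 3, a range of 2.73 within control against a group difference of -1.97 (exact permutation p = 0.1, the smallest that 3 against 3 allows, two-sided, and 0.167 where arrays were exchanged only within slides, again the smallest possible). The median was -0.73 within slide 1 and -3.90 between the 2 arrays of slide 2. It was -0.68 without control replicate 3 and -0.38 with control replicate 2 as the only control array. Of all 20 measured collagen genes outside the muscle list, a set chosen after the values of some were seen, 18 were lower on lead arrays, 7 of them and 0 of the higher ones at unadjusted p under 0.05 (median -0.65, no adjusted p under 0.584). Their mean was -0.41, -1.59 and -0.24 on control replicates 1, 2 and 3 and -1.75, -1.44 and -1.79 on lead replicates 1, 2 and 3, so control replicate 2 lay among the lead arrays. Among them were col10a1a, with all 6 probes lower (median -2.87), and col1a1a, with all 4 lower (-2.22).

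Genes of cholesterol and lipid synthesis were higher on lead arrays, with 33 of 47 measured genes above and a median of 0.27 (camera adjusted p = 0.0146, and adjusted p = 0.93 with an estimated correlation). At unadjusted p under 0.05, 8 were higher and 0 lower. They included hmgcra, the HMG-CoA reductase gene, with a difference of 1.01 ± 0.23 (SE), and the later steps msmo1 (0.91 ± 0.23), nsdhl (1.01 ± 0.27) and sqlea (1.57 ± 0.44), none of which passed adjustment over the list alone (smallest adjusted p 0.121). The mean of the list was 1.07 to 1.22 on the 3 lead arrays and 0.82 to 0.98 on the 3 control arrays. The median was 0.25 within slide 1 (adjusted p = 0.0127) and 0.28 between the arrays of slide 2. The call ended without control replicate 2 (adjusted p = 0.135) and without lead replicate 2 (0.0656, median 0.18).

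Cell cycle and DNA replication genes were also higher on lead arrays, with 49 of 66 above, a median of 0.17 and a camera adjusted p of 0.00974 (adjusted p = 0.93 with an estimated correlation). Among them, 10 were higher and 0 lower at unadjusted p under 0.05, including the proliferation marker mki67 (0.96 ± 0.25 SE), the replication clamp gene pcna (1.28 ± 0.38), the licensing inhibitor gmnn (0.90 ± 0.27) and the cell cycle inhibitor cdkn1ca (0.77 ± 0.21). Of the 8 other mki67 probes 6 had the same sign, and gmnn turned to -0.37 with outlier spots kept. Within slide 1 the list's median was 0.10 (adjusted p = 0.131), and on slide 2 it was 0.44. It was 0.32 without lead replicate 2 and 0.08 without lead replicate 3, and the call ended with the muscle covariate (adjusted p = 0.397, median 0.05). The list's mean was -0.42 on lead replicate 2, inside the range of the control arrays (-0.62 to -0.41).

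Among the oxidative phosphorylation genes, 61 of 77 were higher on lead arrays, with a median of 0.17 (camera adjusted p = 0.00974, and adjusted p = 0.93 with an estimated correlation). The respiratory chain genes with the smallest p were ndufs5 (0.53 ± 0.21 SE), cox7a2a (0.48 ± 0.20), ndufa5 (0.45 ± 0.20) and cox4i1 (0.42 ± 0.20), the last with the same sign at 1 of 2 other probes. The call ended with quantile normalization (adjusted p = 0.593), with normexp and quantile normalization (0.598), with cyclic loess (0.525) and within slide 1 (0.524), where the medians were 0.08, 0.08, 0.06 and 0.07. It also ended without control replicate 3 (0.112, median 0.11), without lead replicate 3 (0.106, median 0.11) and with the muscle covariate (0.487, median 0.08). With median scaling the median was 0.355 (adjusted p = 0.00865). On slide 2 the median was 0.43.

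Neuropeptide genes had a median of 0.38, with 36 of 42 higher on lead arrays (camera adjusted p = 0.0146, and adjusted p = 0.93 with an estimated correlation). The natriuretic peptide gene nppc differed by 1.49 ± 0.54 (SE), pyya by 1.25 ± 0.46, cart4 by 1.33 ± 0.51 and vipb by 3.56 ± 1.57, the last with a control SD of 3.17 and 2 of 3 control arrays well above background. Control replicate 3 set much of this difference. Its mean over the list was 1.05, against 1.83 and 2.19 on the other control arrays and 1.88 to 2.38 on lead arrays, and without it the adjusted p was 0.497 and the median 0.09. The call also ended without control replicate 2 (0.0593), lead replicate 2 (0.0656) or lead replicate 3 (0.0723). The median was 0.01 within slide 1 and 1.08 on slide 2, and it turned to -0.12 with the muscle covariate (adjusted p = 0.948).

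Voltage-gated ion channel genes were lower on lead arrays, with 21 of 30 below and a median of -0.23 (camera adjusted p = 0.00228, and adjusted p = 0.93 with an estimated correlation). The sodium channel genes scn1bb (-0.61 ± 0.21 SE) and scn8ab (-0.80 ± 0.31) and the potassium channel genes kcnc1a (-0.59 ± 0.21) and kcnma1a (-0.57 ± 0.21) had the smallest p. The median was -0.10 within slide 1 (adjusted p = 0.475) and -0.59 on slide 2, and the call ended without control replicate 3 (adjusted p = 0.143). The median was -0.39 without control replicate 2, -0.38 without lead replicate 2 and -0.15 without lead replicate 1, and it turned to 0.11 with the muscle covariate (adjusted p = 0.518). With median scaling it was -0.05 and with normexp -0.12 under both scalings.

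Circadian clock genes had a median of -0.12 on the scale used here and of 0.06 with median scaling, with 29 of 43 lower on lead arrays (camera adjusted p = 0.021, and 0.017 with median scaling, which ranks the list below other genes in both cases). With an estimated correlation the adjusted p was 0.93. The period gene per3 (-0.68 ± 0.24 SE), bhlhe41 (-0.84 ± 0.31), tefb (-0.53 ± 0.25) and hlfa (-0.90 ± 0.47) had the smallest p. The median was -0.34 within slide 1 and 0.05 on slide 2. The call ended without control replicate 1 (adjusted p = 0.102), control replicate 2 (0.135, median 0.00) or lead replicate 2 (0.485, median -0.06), and the median was -0.28 without control replicate 3 or lead replicate 1, -0.21 without lead replicate 3 and -0.46 with the muscle covariate.

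**Figure D3:**
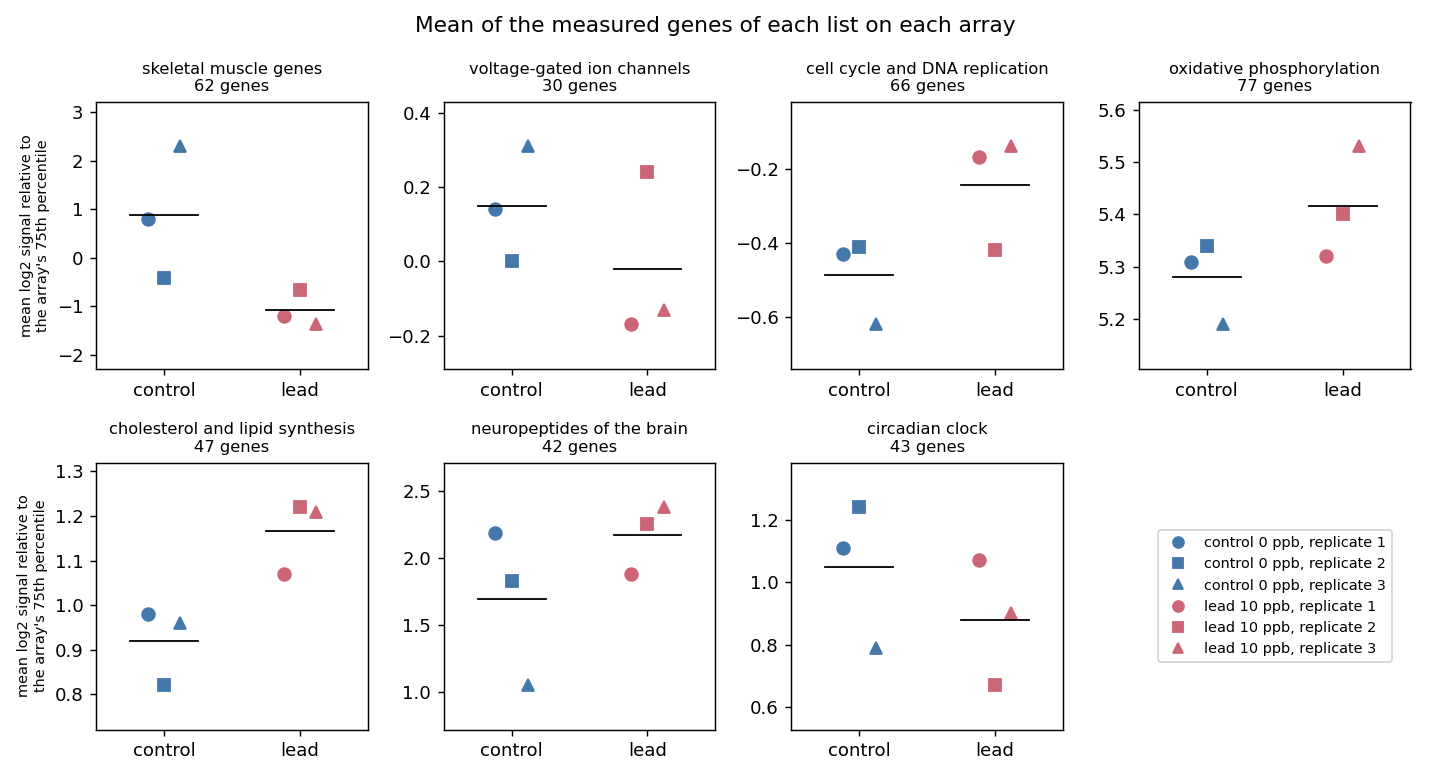
Mean log2 signal, relative to the array's 75th percentile, of the measured genes of the 7 called lists on each array, with a line at the mean of the 3 arrays of a group. The 3 lead arrays lie above the 3 control arrays for cholesterol and lipid synthesis (1.07 to 1.22 against 0.82 to 0.98) and below them for skeletal muscle (-1.37 to -0.67 against -0.42 to 2.3), and the groups overlap in the other 5 panels.

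In all, 7 of 35 lists passed adjustment with the preset correlation, 4 higher and 3 lower on lead arrays. With an estimated correlation 0 lists passed (adjusted p = 0.93 for every list, with 0 at unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p 0.628, with 2 at unadjusted p under 0.05). The arrays can be split 3 against 3 in 10 ways, the real groups included. With the preset correlation 7 of these 10 splits gave 7 or more lists, and the highest other split gave 13. The number of called lists therefore does not set the real groups apart, and the camera calls alone are not evidence of a group effect. With median scaling the medians of lipid synthesis, cell cycle and neuropeptide genes rose to 0.46, 0.36 and 0.565, along with that of all probes. Muscle transcripts were highest on control replicates 1 and 3. With control replicate 2 as the only control array, the camera adjusted p was 0.000831 for muscle, 0.000255 for lipid synthesis, 0.0447 for cell cycle, 0.0298 for neuropeptide, 0.0107 for clock, 0.119 for oxidative phosphorylation and 0.733 for ion channel genes, where the lone control array was assumed to vary like the lead arrays.

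The lists closest to the themes in the series' title did not pass. The 43 Alzheimer's disease-associated genes had a median of -0.07, with 19 higher and 24 lower on lead arrays (camera adjusted p = 0.641). The alpha-secretase gene adam10a was higher by 1.17 ± 0.26 (SE, levels 1.22 ± 0.05 against 0.04 ± 0.39) and reln, the gene of the matrix protein reelin, differed by -1.08 ± 0.44, and neither passed adjusted over the list alone (smallest adjusted p 0.146). The authors' deposited table holds 15 probes of 9 of these genes, 11 of them with a ratio above 0 and 4 below. On the labels used here those 11 were lower and those 4 higher on lead arrays. The 71 nervous system development and neurogenesis genes had a median of 0.15 (adjusted p = 0.53). The Notch ligand gene dlb (1.03 ± 0.32) and the proneural gene ascl1b (0.76 ± 0.26) had the smallest p, and 2 genes were higher and 0 lower at unadjusted p under 0.05. Axon guidance genes had a median of -0.03 (67 genes, adjusted p = 0.354), with sema3aa at 0.94 ± 0.26 (the same sign at 1 of 2 other probes) and the adhesion gene ncam1b at -0.63 ± 0.21. The series' title names these themes, so the choice of these lists is not independent of the study, although their members were fixed before the data were examined. The lists and camera may also differ from the genes and the test behind the study's themes, so these results do not test the themes as the study defined them.

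No list of a transmitter system passed on the scale used here, and the medians were small. Glutamate receptor and synapse genes had a median of -0.06 (33 genes, adjusted p = 0.0805), with the kinase gene camk2b1 at -0.75 ± 0.21 (SE) and the vesicular glutamate transporter gene slc17a6a at -0.72 ± 0.32. This list passed in 6 of 24 other settings, 1 of them the looser threshold of 0.10, with an adjusted p of 0.049 with quantile normalization and 0.0268 with normexp and quantile normalization. The GABA and glycine list stood at 0.01 (23 genes, adjusted p = 0.819), although the GABA transaminase gene abat was at 1.06 ± 0.36 and the synthesis gene gad1b at 0.55 ± 0.27. Of the 7 other gad1b probes 1 had the same sign, and gad1b was at -0.03 with the muscle covariate. The monoamine list (44 genes, median 0.08, adjusted p = 0.826) held the dopamine transporter gene slc6a3 at -0.90 ± 0.28 and the dopamine beta-hydroxylase gene dbh at 1.00 ± 0.32. Acetylcholine genes had a median of 0.04 (16 genes, adjusted p = 0.826), with the receptor genes chrna6 at -0.96 ± 0.40 and chrm2a at 0.51 ± 0.25. Synaptic vesicle genes had a median of 0.08 (44 genes, adjusted p = 0.646), and in this list the synaptotagmin gene syt1b was at 1.69 ± 0.43 and the neurexin gene nrxn2b at -1.02 ± 0.27.

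In glia and vessels, gfap, the astroglial filament gene, was at 4.36 ± 1.13 (SD, n = 3) on lead and 2.71 ± 0.49 on control arrays, and hepacama differed by -0.72 ± 0.24 (SE). Their list of radial glia and astroglia had a median of 0.21 (29 genes, adjusted p = 0.295). Myelin genes had a median of 0.21 (18 genes, adjusted p = 0.265), with ugt8 at 0.78 ± 0.35 and nkx2.2a at 0.56 ± 0.31. Microglia and macrophage genes stood at -0.04 (39 genes, adjusted p = 0.472), with aif1l at 0.61 ± 0.22 and the complement gene c1qc at -1.09 ± 0.61. That list passed in 4 of 24 other settings, with medians of -0.49 without control replicate 3 (adjusted p = 0.00306), -0.17 without lead replicate 1 (0.0429), -0.47 with control replicate 2 as the only control array (0.0196) and -0.71 with the muscle covariate (0.0059). The vascular list had a median of 0.02 (36 genes, adjusted p = 0.641), with abcc9 at -0.75 ± 0.27 and prox3 at -1.51 ± 0.56 (-1.959 to -0.616 over the settings tried). The meninges, matrix and ependyma list had a median of -0.17 (46 genes, adjusted p = 0.0519), with the cilia gene cfap45 at 0.96 ± 0.30 and the laminin gene lamb1a at -1.18 ± 0.37, and it passed in 9 of 24 other settings, among them the threshold of 0.10 and median scaling (adjusted p = 0.00655, median 0.02). The 1 other probe of each of hepacama, prox3, slc17a6a and chrm2a had the opposite sign.

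Lists tied to metals and to cell stress did not pass on the scale used here either. In the haem list (22 genes, median 0.14, adjusted p = 0.53), alad, whose enzyme lead is known to inhibit, was at 0.62 ± 0.19 (SD, n = 3) on lead and 0.01 ± 0.24 on control arrays, and the biliverdin reductase gene blvrb differed by 0.71 ± 0.24 (SE). Metal binding and transport genes had a median of 0.06 (43 genes, adjusted p = 0.897), with pvalb5 at 1.02 ± 0.34 and the zinc transporter gene slc39a13 at -0.93 ± 0.35. The oxidative stress list (52 genes, median 0.15, adjusted p = 0.237) held msrb2 at 0.82 ± 0.29 and gstr at 0.68 ± 0.34, and passed without control replicate 2 (median 0.23, adjusted p = 0.034). In the heat shock and unfolded protein list (64 genes, median 0.08, adjusted p = 0.295), the endoplasmic reticulum genes calr (0.99 ± 0.26) and hyou1 (0.72 ± 0.20) were among 5 genes higher and 0 lower at unadjusted p under 0.05, and 2 of the 4 other calr probes had the same sign. Immediate early genes had a median of 0.19 (52 genes, adjusted p = 0.237), with 6 higher and 2 lower at unadjusted p under 0.05 and pim1 at 0.70 ± 0.21, and the list passed without lead replicate 3 (median 0.26, adjusted p = 0.0232). In the immediate early list socs3a was past the threshold adjusted over the list alone (adjusted p = 0.0252), as it was in the antigen presentation and interferon list (0.0208), which otherwise had a median of 0.06 (43 genes, adjusted p = 0.823) and held mmp9 at -0.49 ± 0.29. The antigen presentation list turned to a median of -0.44 and passed with control replicate 2 as the only control array (adjusted p = 0.0134), and it was at -0.79 with the muscle covariate (0.0704). Over all probes socs3a had an adjusted p of 0.584.

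Apoptosis and p53 genes had a median of 0.05 (48 genes, adjusted p = 0.819), with bmf2 at 0.99 ± 0.27 (SE) and bokb at 0.96 ± 0.30. The chromatin list had a median of 0.07 (54 genes, adjusted p = 0.897), and the histone methyltransferase genes ehmt1a (0.77 ± 0.24) and ehmt1b (0.64 ± 0.22, with the same sign at 1 of 3 other probes) were among 4 genes higher and 0 lower at unadjusted p under 0.05. Ribosomal protein genes had a median of 0.13 here (79 genes, adjusted p = 0.0519) and of -0.04 with quantile normalization, with rps23 at 0.61 ± 0.20 and rpl31 at 0.40 ± 0.19. That list passed in 11 of 24 other settings, among them the threshold of 0.10, median scaling (median 0.31, adjusted p = 0.00865) and quantile normalization (adjusted p = 0.0353), so neither its call nor its sign is settled. The steroid list had a median of 0.16 (28 genes, adjusted p = 0.641) and held the side-chain cleavage gene cyp11a1.1 at 1.34 ± 0.41, with 2 of 3 control arrays well above background, and fkbp5, a glucocorticoid-induced chaperone gene, at -1.39 ± 0.56. With control replicate 2 as the only control array the steroid list passed (median 0.21, adjusted p = 0.0196). The fkbp5 probes differed in sign: of the 4 probes matched by accession the differences were -1.39, -1.18, 1.48 and 0.84. The first of these ran from -1.718 to -0.783 over the settings tried.

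Other tissues at the edge of the dissection were checked with the same lists. Pituitary genes had a median of -0.39 and a mean of 0.24 (10 genes, adjusted p = 0.87), with the hormone precursor gene pomcb at 1.48 ± 0.46 (SE) and pitx1 at -0.79 ± 0.24. The pitx1 probe was well above background on 1 of 3 control arrays and on all 3 lead arrays, although its signal was lower on lead arrays. Its difference was -0.04 with normexp and the 75th percentile. Photoreceptor and retina genes had a median of -0.22 (40 genes, adjusted p = 0.272), with asmt2 at 0.78 ± 0.27 and rlbp1b at -1.35 ± 0.52, and this list passed without control replicate 3 (median -0.38, adjusted p = 0.0273) and with median scaling (median -0.04, 0.0484). Blood genes had a median of -0.15 (20 genes, adjusted p = 0.737), with cahz at 0.60 ± 0.27 and the transferrin receptor gene tfr1a at -1.08 ± 0.44, the latter well above background on 2 of 3 lead arrays. The blood list turned to a median of 0.33 within slide 1 (adjusted p = 0.0535), against -0.76 on slide 2, and passed with control replicate 2 as the only control array (median 0.34, adjusted p = 0.0227) and with the muscle covariate (median 0.73, adjusted p = 5.09e-05). Liver and plasma protein genes stood at -0.19 (25 genes, adjusted p = 0.237), with vtg4 at -0.87 ± 0.49 (the same sign at 1 of 3 other probes) and fabp10a at 0.75 ± 0.45, and passed with median scaling (median -0.01, adjusted p = 0.0484). Oocyte and gonad genes had a median of 0.12 and a mean of -0.06 (22 genes, adjusted p = 0.853), with sycp3 at -1.14 ± 0.43 and amh at 0.47 ± 0.23.

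The authors' deposited table lists 4930 probes, 1804 with a ratio above 0 and 3126 below. Its largest positive ratios were those of MYH4 (5.14), ARID3B (5.07), CKM (4.92), MYL1 (4.88) and MYLPF (4.71), 4 of which are muscle genes. On the labels used here MYH4 was 37.2-fold and MYLPF 27.5-fold lower on lead arrays. CKM and MYL1, which were not well above background on any lead array, were 31.9-fold and 31.0-fold lower on the scale used here. Over the settings tried the log2 differences of MYH4, MYLPF, CKM and MYL1 were as small as -1.448, -1.283, -1.752 and -2.014. Only 1 of the 3 control arrays had an unflagged value for ARID3B. The largest negative ratios in the authors' deposited table were GGCT (-6.70), TSPAN9 (-3.73), EMX1 (-3.07), FKBP5 (-3.00) and MEI4 (-2.88). On the labels used here EMX1, a forebrain transcription factor gene well above background on 2 of 3 control arrays, was 7.95-fold higher on lead arrays. The probe named FKBP5 was 7.58-fold higher. MEI4, not well above background on any control array, was 6.99-fold higher on the scale used here. Over the settings tried the log2 differences of these 3 probes were as small as 1.378, 2.51 and 0.708, in that order. The table holds only probes with a listed p-value of at most 0.05, and its ratios mirror those of these same arrays. A high share at unadjusted p under 0.05 follows from that and is not independent evidence. Of the listed probes 4340 were tested and 3817 (87.9%) had an unadjusted p under 0.05 in the limma fit, and 1, that of GGCT, passed adjustment. Within slide 1 that number was 2310, without lead replicate 1 it was 2486, and with control replicate 2 as the only control array it was 1654. By list, the authors' deposited table holds 40 muscle probes, 38 with a ratio above 0, 37 lipid synthesis probes, 34 below 0, 23 cell cycle probes, all below 0, and 16 heat shock probes, all below 0. On the labels used here a ratio above 0 stands for a lower, and one below 0 for a higher, signal on lead arrays.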

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

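Fits with control replicate 2 as the only control array, and with the mean of the muscle genes as a covariate, were chosen after the data were examined. Of the 115 named genes, 109 kept the sign of their difference under every setting tried, and the other 6 changed it under 1 setting each. The named genes were chosen on these same arrays by small p, many of them with groups that did not overlap. Leaving out 1 array cannot turn the sign of such a gene, so this number is not evidence for the differences. The number of probes past adjustment, 1 over all arrays, was 0 with no filter on dim probes, with probes well above background on all 6 arrays, with slide as a block, within slide 1, with control replicate 2 as the only control, with the muscle covariate and without any 1 array (0 to 0), and it was 4 with no moderation of the variance. At unadjusted p under 0.05 the number without 1 array ran from 4701 to 7617. With at least 1.5-fold as well it was 3772 with normexp and quantile normalization, 3857 with normexp and the 75th percentile, and 4609 with no moderation, and the offset of normexp shrinks folds of dim probes by construction. With outlier spots kept 59.9% of 6107 unadjusted calls were higher on lead arrays, against 43% of 7403.

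Probes of the authors' deposited table at unadjusted p under 0.05 numbered 2310 within slide 1, 1654 with control replicate 2 as the only control, 1306 with the muscle covariate and 2486 to 3118 without 1 array. Called lists numbered 11 with median scaling, 3 within slide 1, 4 with the muscle covariate, 0 with an estimated correlation and 0 with fry. The median of the clock genes changed sign with median scaling (adjusted p = 0.017) and without control replicate 2, and its adjusted p without 1 array ran from 0.0029 to 0.485. With the muscle covariate the medians of the muscle genes (adjusted p = 0.551), ion channels (0.518) and neuropeptides (0.948) changed sign. Because this covariate separates the groups, a lost call or a changed sign does not tell muscle RNA from lead. Lists not called over all arrays passed in 39 of 671 list and setting pairs, most often ribosomal proteins, meninges and glutamate genes. The blood and microglia lists passed in both of the fits chosen after the data were examined. The causes were not tested, apart from fewer arrays in the fits that leave some out and the muscle genes' own mean in the covariate.

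The replicate numbers gave no pairing: deviations from the group mean correlated, across probes, at 0.053 for replicate 1, -0.07 for replicate 2 and 0.275 for replicate 3, while pairs of other numbers on the same slide were at 0.13 and 0.225 and all 4 pairs across slides lay between -0.27 and -0.05. With the replicate number as a block 0 probes passed adjustment and 6928 had an unadjusted p under 0.05. List tests were not run with slide as a random block or without moderation, and array position was not fitted because it follows the groups. Slide 2 alone, with 1 array per group, gives values and no test. The median difference moved with probe brightness: it was -0.20 in the dimmest 17952 probes and 0.07 in the brightest 17952. Negative control spots were brightest on control replicates 1 and 3 (mean log2 signal 2.99 and 2.47), and whether this gives the trend was not tested.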

Other observations

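The tests of the cell cycle genes after cyclic loess and over other splits, and the number of lists over other splits, were chosen before their result was seen. All other tests in this part, including the fits with control replicate 2 as the only control array and with the muscle covariate, were chosen after the data were examined. Each explanation is a hypothesis.

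The sign of the authors' deposited table was opposite for 100% of its comparable probes, with a correlation of -0.998 across probes. An exchange of only some labels is argued against, because for each of the other 9 splits of the 6 arrays at most 2% of the listed probes lay within 0.01 of the split's ratio in either sign, and 96% did for the real split. A table that gives control over lead, and an exchange of the labels of all 6 arrays, cannot be told apart, because both mirror every value alike. If the labels were exchanged, every difference given as lead minus control would change sign, while sizes and p would stay.

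Skeletal muscle genes were higher on control arrays, most on control replicate 3 (mean 2.3) and control replicate 1 (0.80). Scaling is argued against, since the median difference stayed at -1.30 or below under the 5 other scalings. Muscle tissue carried along with some brains was neither singled out nor excluded. The first component of the muscle genes held 75% of their variance between arrays, more than 99.4% of 1000 random lists matched on mean signal (95th percentile 61.8%), but lead acting on these genes together would give the same. Among them pvalb4 and mylpfa reached 5.53 and 5.67 on control replicate 1 and 6.47 and 6.14 on control replicate 3. These 2 did not separate the groups, since they were at 2.1 and 1.82 on lead replicate 2 and at 1.76 and 1.70 on control replicate 2. The order of control replicates 1 and 3 differed between genes, with myhz2 at 6.09 and 4.79. Of the 62 genes, 60 were well above background on lead replicate 3 and 53 on all 3 lead arrays, against 60 on all 3 control arrays. The filter on dim probes favours detected genes, and carried muscle tissue would be detected as well. Detection therefore does not tell whether brain cells express these genes. Among the list's brightest probes, mybpc2b and acta1a differed by 0.06 and -0.52. Lead exposure stays open as well, because the range within control arrays, 2.73, exceeded the group difference of -1.97 while the groups did not overlap.

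Cell cycle genes were higher on lead arrays with a median of 0.17. A trend of the ratio with probe brightness was not settled by the rule set beforehand. After cyclic loess normalization the camera adjusted p stayed under 0.05, at 0.00261 (8.01e-05 to 0.93 over the settings tried). The median rose to 0.23, a larger move than the rule allowed for counting against the trend. The list's difference was not lost with that normalization. Muscle RNA on control replicates 1 and 3 stays open: with control replicate 2 as the only control array the median was 0.144, below the full value and above 0, and with the muscle covariate it was 0.05. Lead exposure was not excluded and not singled out. Another split, control replicates 1 and 3 with lead replicate 2 against the rest, gave a median of 0.288 against 0.173 for the real one. The largest median thus did not come from the split by group. The standard error of the group difference, 0.11, is that of the list's mean between the real groups. It does not measure a difference between the medians of splits that share arrays. Whether the larger median counts against exposure is therefore not settled.

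With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 probe past adjustment and the highest other split 8, with 6 of 10 splits at 1 or more. The real split gave 7403 probes at unadjusted p under 0.05 against at most 6603 in another split, and 6937 with at least 1.5-fold against at most 6551, so 1 of 10 splits reached each of these. For lists, 7 of 10 splits gave 7 or more, and the highest other split gave 13. The split with 13 lists set both arrays of replicate 1 and control replicate 2 against the rest. These splits exchange arrays between slides. Of the 6 that keep the slides balanced, the highest other gave 6 probes past adjustment, 4793 at unadjusted p under 0.05, 4452 with at least 1.5-fold and 8 lists, and 6 splits are also too few.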
